A study of Homo sapiens with 3 samples.

How the data were processed

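The series comprised 3 libraries from primary human endometrial stromal cells treated with estradiol, medroxyprogesterone acetate and cAMP: 1 PGR ChIP, 1 FOSL2 ChIP and 1 input. Samples were grouped by the antibody in the labels. Per the labels' protocols, sonicated chromatin was immunoprecipitated, adapters were ligated, fragments of 200 to 300 bp were cut from a gel, and the libraries were amplified with 18 PCR cycles and sequenced on an Illumina Genome Analyzer. Per the submitters' processing notes, reads were aligned with BWA (version not given in the sources used here) to GRCh37.p2. The peak caller, its threshold, the handling of duplicate reads and the use of the input library are not given in the sources used here. These steps bear on the number and length of regions: a list called at a looser threshold is longer and meets the other list more often, and PCR duplicates kept after 18 cycles can raise a region's value.

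For each antibody the authors deposited 1 list of regions without a header, with chromosome, start, end, a whole-number score and a region name. The deposited score is the authors' own value per region. Nothing in the labels or files says whether it is a count, a height or a statistic, so it was treated as a score and used only for ranks within a list. Starts count from 0 in the files and are given here from 1. The deposited lists held 8690 PGR and 24298 FOSL2 regions. Regions on chromosomes 1 to 22 and X were analysed, 8689 and 24295. No region overlapped another of its own list. Each list comes from a single library, so the authors' calls could not be compared between replicates.

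The build was checked on the files. The highest end on chromosome 1 was 249168879, within the 249250621 bp of GRCh37 and beyond the 248956422 bp of the GRCh38 sequence at hand, and no chromosome held a region past its GRCh37 end. Coordinates were not converted between builds. The genome sequence and gene annotation at hand are of GRCh38, so no gene name, gene feature or sequence motif was tied to a region, and the comparisons planned for gene lists, gene features, motifs and genes with both factors are not analysed here. Regions are named by coordinates and by the cytogenetic band of their midpoint. Bands came from the GRCh37 table of the R package circlize 0.4.16, whose last band ended at the GRCh37 chromosome end on 23 of 23 chromosomes, and chromosome lengths came from GenomeInfoDb 1.38.1.

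Before the data were examined, the overlap in both directions, the shares by score rank, the alternatives described here and the rule for named items were fixed. The rule named the genes tied to the 10 highest regions of each list and to the 10 overlapping pairs with the best summed rank. It also named those tied to the 5 highest regions of each list without the other factor. With no GRCh37 annotation, the regions and pairs themselves are named here instead. For the summed rank, each rank was divided by the length of its list. The parts of the rule about fixed genes and gene lists were not applied. All other comparisons were chosen after the data were seen: distances between centres, the correlation of scores over pairs, pairs in the top decile of both lists, the contrast of the 10 highest FOSL2 regions with the rest of their decile, the map at 11q23.2, and the comparisons over 500 kb windows, chromosomes and bands with the windows and bands named from them.

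Overlap meant at least 1 shared bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals and densities exact 95% Poisson intervals. These cover counting error only and treat regions as independent, which neighbouring regions are not. The overlap was tested one-sided against 100000 random placements of the PGR regions with their lengths on their own chromosomes. Assembly gaps were not excluded, since no GRCh37 sequence was used. On simulated lists of 8689 regions with 1%, 5% and 20% planted overlap, the test recovered 0.969%, 5.21% and 20.0%, and 2 of 20 lists with none planted had p under 0.05. Regions of the simulated lists were placed uniformly, as in the test itself, so the error rate for clustered lists such as these was not examined. Alternatives were coverage of at least 50% of a region, centres within 250 bp, the upper 50% of each list by score, a FOSL2 list shortened to the length of the PGR list, autosomes only, shifts of 10 to 100 kb, and merging of regions within 100 bp. Distances were compared with 20 shifted or placed copies of the list, and the interval of the score correlation came from 1000 bootstrap resamples of pairs. Deciles were formed by score or length with ties broken by position. In the band comparison, dark bands were the stain classes 75% and 100%, light bands were unstained, and 0.5 was added to each count per chromosome. The sign-flip test drew 100000 flips over autosomes and treats chromosomes as units. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.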

Results

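Binding regions of 2 transcription factors were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in primary human endometrial stromal cells that were being driven to decidualize. Decidualization is the conversion of the fibroblast-like stroma of the uterine lining into the secretory decidua of pregnancy. The cells were exposed to 10 nM 17β-estradiol, 100 nM medroxyprogesterone acetate, which is a synthetic progestin, and 1 mM cAMP. One library was made with an antibody against the progesterone receptor (PGR), the nuclear receptor through which progesterone acts. Another was made with an antibody against FOSL2, also called Fra-2, a FOS-family subunit of the AP-1 transcription factor. An input library without antibody completed the series and is not analysed here as a track of its own. With 1 library per factor there were no replicates, so every interval and test below describes these lists of regions and not the spread between cultures. The read depth of the libraries is unknown from the region lists.

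The first question was how many regions each factor occupied and where they lay. The PGR list held 8689 regions on chromosomes 1 to 22 and X, and the FOSL2 list held 24295. PGR regions had a median length of 710 bp (interquartile range 572 to 861 bp) and together covered 6.45 Mb, or 0.212% of these chromosomes. FOSL2 regions were shorter, with a median of 588 bp (interquartile range 473 to 714 bp), and covered 14.8 Mb, or 0.488%. The authors' score ran from 5 to 240 in the PGR list, with a median of 15, and from 5 to 289 in the FOSL2 list, with a median of 18. It is the authors' own value per region, of unstated scale, and was used only to rank regions within a list. Positions are on GRCh37, and regions are named by cytogenetic band and not by gene, since no gene annotation of that build was used here.

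The highest PGR scores were at band 11q23.2. The region with the highest PGR score, 240, was on chromosome 11 from 114,049,562 to 114,050,674, and the second, with a score of 208, lay on the same chromosome from 114,033,200 to 114,035,272. Within 100 kb to either side of the centre of the first there were 10 PGR regions and 9 FOSL2 regions, and 6 of the 10 PGR regions were overlapped by FOSL2. The third PGR region by score (190) was at 3q28, on chromosome 3 from 188,665,084 to 188,666,480. A score of 177 was shared by regions at 1q32.1 (chromosome 1, 204,057,811 to 204,058,820) and 2p23.2 (chromosome 2, 28,849,594 to 28,850,399). The remaining 5 of the 10 highest PGR regions were at 3q13.11 (score 176), at 20q13.12 (scores 170 and 161, centred within 20 kb of each other), at 1p36.23 (score 168) and at 1q21.1 (score 166). Of these 10 regions, 8 were overlapped by a FOSL2 region (exact 95% binomial interval 44.4% to 97.48%), and the regions at 1q32.1 and 2p23.2 were not. In the whole top decile of the PGR list by score, these 10 included, the share was 43.2% (39.9% to 46.6%). The difference was not tested. The nearest FOSL2 centre was 15.6 kb away from the 1q32.1 region and 5.42 kb away from the 2p23.2 region. The next highest PGR regions without FOSL2 were at 8q11.21 (chromosome 8, 48,571,552 to 48,572,837, score 154), 9q22.32 (chromosome 9, 96,897,041 to 96,898,076, score 152) and 17p13.1 (chromosome 17, 8,057,331 to 8,058,349, score 150). The 1q21.1 and 8q11.21 regions lie within 5 Mb of a centromeric or variable band.

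**Figure D1:**
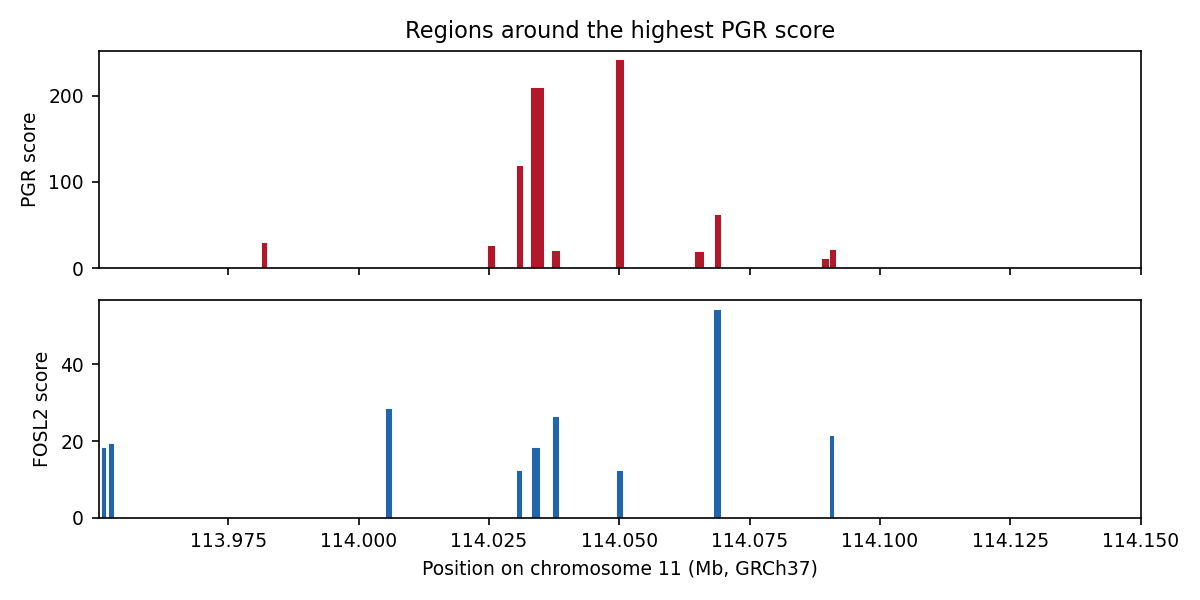
PGR regions (upper panel) and FOSL2 regions (lower panel) within 100 kb of the centre of the highest-scoring PGR region, by position on chromosome 11 in Mb (GRCh37). Each bar spans 1 region and its height is the authors' score, on an axis of its own in each panel; the PGR scores of 240 and 208 stand over FOSL2 scores of 12 and 18, and the highest FOSL2 score of 54 stands over a PGR score of 61.

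The FOSL2 list was headed by other loci. Its highest score, 289, was at 1q22 on chromosome 1 from 156,186,116 to 156,186,771, followed by 286 at 21p11.2 (chromosome 21, 9,825,338 to 9,827,689) and 246 at 1p22.2 (chromosome 1, 91,852,665 to 91,853,264). Neighbouring regions at 20p11.1 had scores of 210 (chromosome 20, 26,189,668 to 26,190,614) and 148 (chromosome 20, 26,188,707 to 26,189,493). The others of the 10 highest were at 11q14.1 (188), 17q12 (166), 12p12.2 (165), 2q31.1 (136) and 12q13.3 (129). None of these 10 was overlapped by PGR (0 of 10, exact 95% interval up to 30.8%), against 23.3% (21.6% to 25.01%) of the other 2419 regions in the top decile of the list. A draw of 10 from that decile holds no overlapped region with an exact hypergeometric probability of 0.0712, so the difference did not pass 0.05. Among the 10, 3 lay within 5 Mb of a centromeric, variable or stalk band, against 6.95% of the other regions in the decile.

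The comparison the design implies is whether both factors occupied the same places. FOSL2 regions overlapped 3636 of the 8689 PGR regions by at least 1 bp, which is 41.8% (exact 95% interval 40.8% to 42.9%). Seen from the longer list, 3677 of the 24295 FOSL2 regions, or 15.1% (14.7% to 15.6%), were overlapped by PGR. Placing the PGR regions at random on their own chromosomes gave a mean of 96.3 overlapped regions, or 1.11%, and at most 145 in 100000 draws. The observed number was 37.8 times that mean (one-sided permutation p = 1e-05, the smallest that 100000 draws can give). Each PGR region was also shifted separately by a random 10 to 100 kb. This keeps it in its neighbourhood and leaves the FOSL2 list in place, but not the close spacing of PGR regions. The shifts gave a mean of 204 overlapped regions (2.35%), so the observed number was then 17.8 times the mean (permutation p = 1e-05). The share depended on which FOSL2 regions were kept: with only the 8689 highest-scoring ones, 19.0% (18.2% to 19.8%) of PGR regions were overlapped, 44.9 times the placed mean. This cut changes both the length of the FOSL2 list and the scores in it. All these intervals cover counting error only.

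Overlapping regions of both factors had centres closer together than overlaps produced by shifting. The centre of an overlapped PGR region lay a median of 80.0 bp (interquartile range 36.0 to 141 bp) from the nearest FOSL2 centre, and 60.3% (58.6% to 61.9%) of the 3636 lay within 100 bp. Overlaps produced by the 10 to 100 kb shifts had a median of 343 bp, with 14.1% within 100 bp, over 20 shifted copies of the list. PGR regions without a FOSL2 overlap were a median of 20.7 kb (interquartile range 7.13 to 54.8 kb) from the nearest FOSL2 centre. Random placement of these regions on their chromosomes, counting also those that then met a FOSL2 region, gave a median of 70.3 kb. After local shifts of the whole PGR list, the regions that met no FOSL2 region were a median of 23.8 kb from one.

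**Figure D2:**
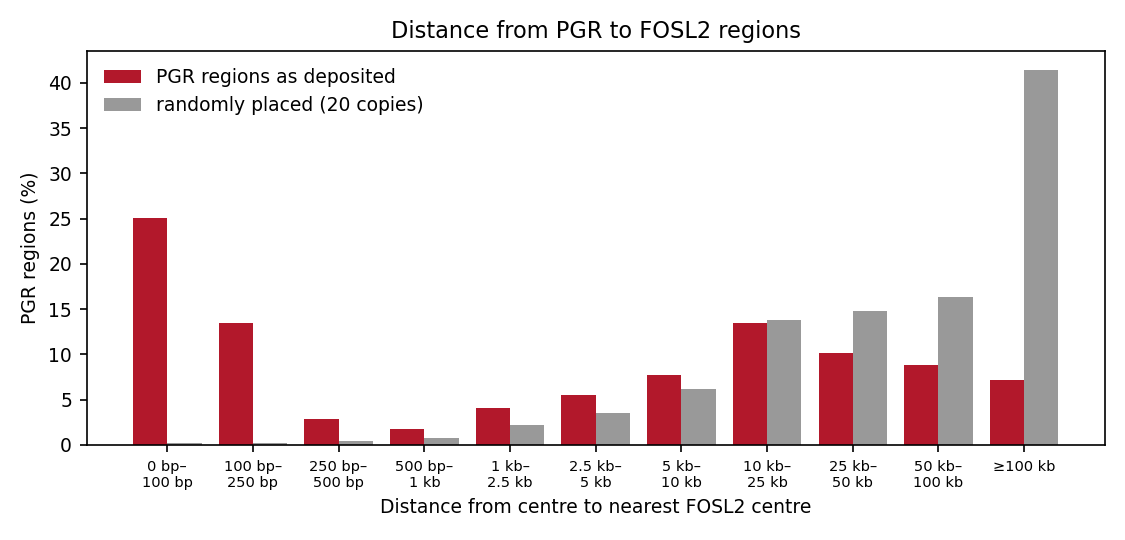
Percentage of PGR regions (vertical axis) by the distance from their centre to the nearest FOSL2 centre (horizontal axis, unequal classes in bp and kb), as deposited (red) and over 20 randomly placed copies (grey). Of the deposited regions 25.02% lie under 100 bp and 13.5% from 100 to 250 bp, against 0.18% and 0.246% of the placed ones, while 41.5% of the placed regions and 7.16% of the deposited ones lie 100 kb or more away.

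Several loci ranked high for both factors. The best summed rank belonged to 1q21.1 on chromosome 1, where a PGR region from 145,083,216 to 145,084,906 with a score of 166 and a FOSL2 region from 145,083,183 to 145,084,846 with a score of 82 had centres 46 bp apart. At 7q22.1 on chromosome 7 a PGR region from 100,743,297 to 100,744,117 and a FOSL2 region from 100,743,246 to 100,744,080 each had a score of 105. That score ranked 66 in the PGR list and 23 in the FOSL2 list. At 16p12.1 on chromosome 16 a PGR region from 24,712,081 to 24,712,652 (score 141) lay on a FOSL2 region from 24,712,089 to 24,712,708 (score 79). The other 7 of the 10 best pairs were at 14q23.1, 11q24.1, 18p11.23, 6p21.1, 1p11.2, 11q12.2 and 6q12, with PGR scores from 71 to 113 and FOSL2 scores from 62 to 80. The pairs at 1q21.1, 1p11.2 and 6q12 lie within 5 Mb of a centromeric or variable band. In the whole lists, 8167 of the 8689 PGR regions and 22808 of the 24295 FOSL2 regions lie farther from centromeric, variable and stalk bands. Whether read pile-ups in repeats, present in both libraries, gave these pairs was not tested. The partner of the top PGR region at 11q23.2 had a FOSL2 score of only 12, rank 19137 of 24295, but FOSL2 partners of the top decile of PGR regions had a median score of 24, against 21 for all partners. Over all 3692 overlapping pairs the scores had a Spearman's rho of 0.18 (95% bootstrap interval 0.15 to 0.21) across pairs, which are not independent replicates. Pairs in the top decile of both lists numbered 80, against 65.0 if the ranks were independent.

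The share of regions that met the other factor varied with rank in each list. In the PGR list it was 29.5% (26.4% to 32.6%) in the lowest decile of the score and 48.6% (45.2% to 51.9%) in the eighth, and it was 43.2% (39.9% to 46.6%) in the highest. In the FOSL2 list it was 12.9% (11.6% to 14.3%) in the lowest decile and 23.2% (21.6% to 24.95%) in the highest. Length separated the regions more than score did. Only 19.4% (16.9% to 22.2%) of the shortest decile of PGR regions were overlapped, and 65.2% (61.9% to 68.4%) of the longest. In the FOSL2 list these shares were 3.7% (2.99% to 4.53%) and 34.7% (32.8% to 36.6%). The median PGR score was 16 in overlapped and 15 in other regions, while the median length was 781 bp against 658 bp. FOSL2 regions with PGR had a median score of 21 and a median length of 696 bp, against 18 and 569 bp without.

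**Figure D3:**
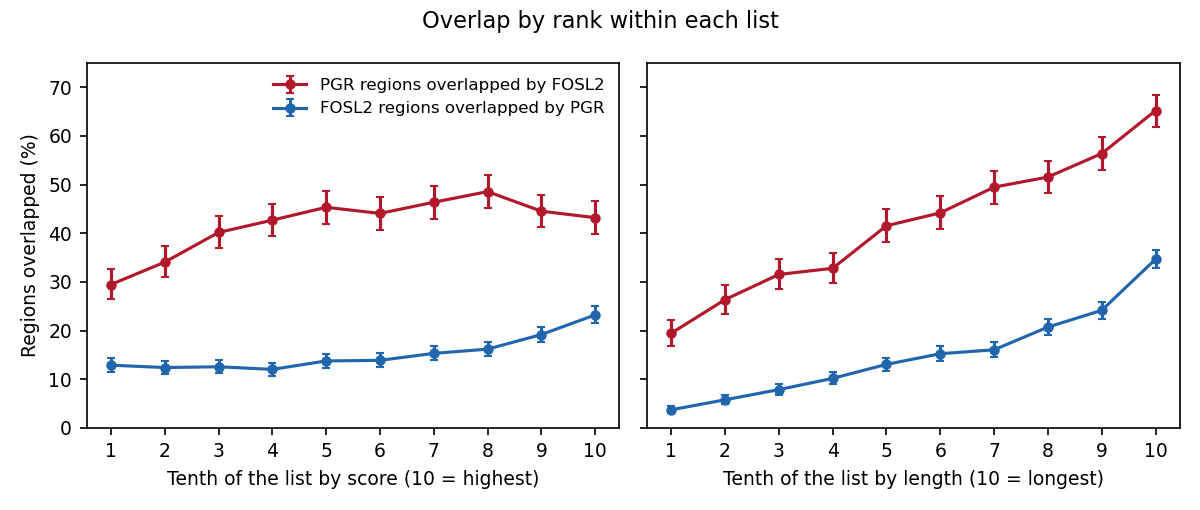
Percentage of PGR regions overlapped by FOSL2 (red) and of FOSL2 regions overlapped by PGR (blue) in each decile of their own list, ranked by the authors' score (left) or by length (right), as points with exact 95% binomial intervals. The PGR share lies between 29.5% and 48.6% across score deciles and between 19.4% and 65.2% across length deciles.

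Regions of both factors were crowded into the same parts of the genome. Over 5776 autosomal windows of 500 kb the PGR list averaged 1.47 regions with a variance of 4.1, and the FOSL2 list averaged 4.13 with a variance of 16.5. Their counts per window had a Spearman's rho of 0.68 across windows, which are not independent. All autosomal windows were counted, also those in centromeric bands, which held 0.132 PGR and 0.468 FOSL2 regions per Mb. Windows nearly empty in both lists can raise this rho. There were 1219 windows with neither factor, and only 110 windows held PGR without any FOSL2 region. The most PGR regions, 19, fell in the window from 30,000,001 to 30,500,000 at 8p12 on chromosome 8, together with 19 FOSL2 regions. The window from 8,000,001 to 8,500,000 at 1p36.23 on chromosome 1 followed with 18 PGR regions, and it held the most FOSL2 regions, 30. At 13q14.11 on chromosome 13, the window from 40,500,001 to 41,000,000 held 17 PGR and 22 FOSL2 regions. Other windows with many FOSL2 regions held fewer PGR regions than these, though more than the mean of 1.47, such as 238,000,001 to 238,500,000 at 2q37.3 on chromosome 2 with 28 FOSL2 and 5 PGR regions, and 128,000,001 to 128,500,000 at 11q24.3 on chromosome 11 with 23 and 3.

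The balance of both factors varied by chromosome and by cytogenetic band. Over all autosomes there were 35.6 PGR regions per 100 FOSL2 regions. Chromosome 4 had the most, 43.1 per 100 (577 and 1339 regions), and chromosome 19 the fewest, 20.1 per 100 (87 and 433 regions). PGR made up 30.1% (exact 95% interval 28.1% to 32.2%) of the regions of both lists on chromosome 4 and 16.7% (13.6% to 20.2%) on chromosome 19. Giemsa-dark bands are the gene-poor, AT-rich parts of chromosomes as a rule. FOSL2 density was 10.2 regions per Mb (95% Poisson interval 9.97 to 10.3) in unstained bands and 5.91 (5.69 to 6.14) in the darkest class. PGR density was 3.43 per Mb (3.33 to 3.53) in unstained bands, 3.24 (3.07 to 3.43) in the class stained 75% and 2.36 (2.23 to 2.51) in the darkest. The ratio of density in the 2 darkest classes to that in unstained bands was 0.806 for PGR and 0.667 for FOSL2. The log2 ratio of dark to unstained counts was higher for PGR than for FOSL2 by 0.26 ± 0.24 (SD, n = 20 autosomes with dark bands), and it was higher on 16 of the 20 (two-sided sign-flip permutation p = 0.00026 over chromosomes). No single band stood apart: of 756 bands, 61 had an exact binomial p under 0.05 for the balance of both factors and 0 passed after Benjamini-Hochberg adjustment, with a lowest adjusted p of 0.212. The share of PGR regions overlapped by FOSL2 was 42.1% in unstained bands and 42.6% in the darkest class.

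**Figure D4:**
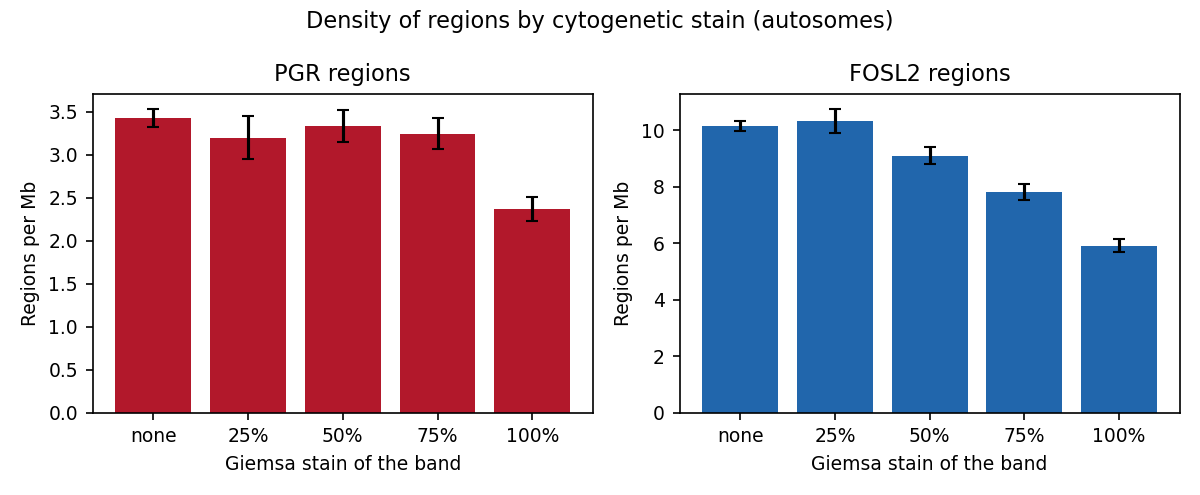
Regions per Mb of autosomal sequence (vertical axes, different scales) by the Giemsa stain class of the cytogenetic band (horizontal axis, none to 100%) for PGR (left) and FOSL2 (right), as bars with 95% Poisson intervals of the counts. FOSL2 density is 10.2 per Mb in unstained bands and 7.81 and 5.91 in the 2 darkest classes, while PGR density is 3.43, 3.24 and 2.36.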

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

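The tests of score correlation, of the 10 highest FOSL2 regions and of Giemsa bands were chosen after the data were seen, and the bounds for the shift and score correlation tests of the overlap were set after their results were seen. The PGR list held 1 region on the mitochondrial genome, outside the chromosomes compared, from position 1 to 4475. Its score of 209 would have ranked second in the list, its length exceeded the 3723 bp of the longest nuclear PGR region, and the FOSL2 list held 0 regions there.

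The overlap of PGR with FOSL2, 37.8 times the mean of random placement, was weighed against technical explanations. Regional density of both lists on scales wider than 100 kb would have kept the overlap under shifts of 10 to 100 kb. The observed number was 17.8 times the shifted mean. Every shift was at least 10 kb and each region moved separately, so crowding on smaller scales was not tested. Background common to both libraries, such as extra reads from open chromatin, could give coinciding regions without binding, and it stays open. The Spearman's rho of 0.18 between scores lay between the bounds set afterwards for and against this explanation. Binding of both factors at the same sites could also give a positive rho, so this correlation cannot decide. Neither the input library nor a ChIP of an unrelated factor was compared.

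The absence of PGR from the 10 highest FOSL2 regions had an exact hypergeometric probability of 0.0712 and may be chance. Read pile-ups in repeats near centromeres could account for 3 of the 10 regions, those at 21p11.2 and 20p11.1, a number equal to the upper limit of 95% of random sets of 10, so this stays open for them. The other 7 lie more than 5 Mb from such bands, and pile-ups in repeats elsewhere were not tested for them. The 10 were a median of 35.9 kb from the next FOSL2 region, against 14.96 kb in random sets (95% of sets 4.61 to 44.5 kb), so isolation beyond chance was not shown. The regions at 20p11.1 are each other's nearest, with centres 1.04 kb apart, so a single locus enters that median more than once and lowers it. FOSL2 binding without PGR, which the design names by its antibodies, stays open and untested.

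PGR regions were less depleted than FOSL2 regions in dark Giemsa bands. With the FOSL2 list shortened to the length of the PGR list, the log2 difference was 0.51, against 0.27 for the full lists. This cannot decide whether a longer FOSL2 list reaching weaker regions explains the difference, since only FOSL2 lost its lower-scoring regions. That cut lowered the FOSL2 ratio of dark to unstained density from 0.667 to 0.565, with PGR kept at 0.806. With the lower-scoring part of each list left out, the ratios were 0.707 for PGR and 0.595 for FOSL2. The log2 difference was then 0.25. The sign-flip permutation p of 0.00026 over 20 autosomes describes these 2 lists, was computed after the data were seen and does not stand for replicate libraries. A difference in GC bias between the libraries, each from 18 PCR cycles, could not be tested without the GRCh37 sequence. Such a bias, the longer FOSL2 list and a difference between the factors all remain possible explanations.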

How the results depend on the processing

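The excess of PGR regions overlapped by FOSL2 kept its direction and its side of the threshold under all 10 alternatives, with observed-to-placed ratios from 17.8 (shifts of 10 to 100 kb) to 93.1 (centres within 250 bp). Leaving out the 10 highest FOSL2 regions is no support, since 0 of them were overlapped and the count of 3636 could not change. The share itself was 41.8% in the main setting and ranged down to 19.0% with the FOSL2 list shortened to the length of the PGR list and 29.8% with the upper 50% of each list. The share of FOSL2 regions overlapped by PGR, 15.1%, became 14.6% when 50% of the FOSL2 region had to be covered, 10.7% with the upper 50% of each list and 19.0% with the shortened FOSL2 list, which keeps the regions of highest score. Coverage of 50% is a stricter criterion and can only lower the share. The shortened FOSL2 list was set against the full PGR list, and there the share was 12.9% in the lowest FOSL2 score decile and 23.2% in the highest. The upper 50% setting also cut the PGR list, which can only remove overlaps. The share in the top PGR decile, 43.2% by score, was 65.2% by length, 39.3% by score with centres within 250 bp, and 50.1% by length with centres within 250 bp. In the FOSL2 list the 23.2% by score became 34.7% by length and 30.6% by length with centres within 250 bp. The cause of these differences by length was not tested. The band difference kept its direction and side under 4 alternatives (mean log2 difference 0.15 to 0.47, sign-flip permutation p from 1e-05 to 0.00736). Alternatives on centromeric bands, on the 10 highest FOSL2 regions, on centres by decile and on Giemsa bands were added after seeing the data. Ranking by another score was not run because each list has 1 score, and the alternatives for gene features, motifs, gene lists and genes with both factors were not run, since they need a GRCh37 genome or annotation. With 1 library per factor no replicate could be left out, and the depth of the libraries is unknown.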

Other observations

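The length of a region was tied to the presence of the other factor even where interval reach was taken out. With centres within 250 bp as the criterion, 18.1% (exact 95% binomial interval 15.6% to 20.8%) of the shortest decile of PGR regions had a FOSL2 centre, against 50.1% (46.7% to 53.5%) of the longest. In the FOSL2 list these shares were 3.21% (2.55% to 3.99%) and 30.6% (28.8% to 32.5%). By score under the same criterion, the PGR shares were 27.2% (24.2% to 30.2%) in the lowest decile, 44.2% (40.9% to 47.6%) in the eighth and 39.3% (36.0% to 42.6%) in the highest. Score and length of a region had a Spearman's rho of 0.38 across PGR regions and 0.41 across FOSL2 regions, which are not independent replicates.

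Crowded loci differed in how often both factors met in them. Of the 18 PGR regions in the window from 8,000,001 to 8,500,000 at 1p36.23 on chromosome 1, 14 were overlapped by FOSL2. In the window from 30,000,001 to 30,500,000 at 8p12 on chromosome 8 it was 7 of 19, although PGR and FOSL2 regions were equally many there. At 13q34 on chromosome 13, from 110,500,001 to 111,000,000, it was 4 of 14, with 14 FOSL2 regions present. These windows are among the 8 listed for their number of PGR regions after the data were seen. The windows at 1p36.23 and 13q34 had the highest and the lowest share of the 8. Between them lay 10 of 17 at 13q14.11, 7 of 14 at 10q21.2, 5 of 15 at 10p15.1, and 5 of 13 at both 10p11.23 and 1q31.2. The difference between windows was not tested. By autosome, the share of PGR regions overlapped ran from 35.5% on chromosome 17 to 54.8% (exact 95% interval 44.2% to 65.2%) on chromosome 22.

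Bands with the lowest p for the balance of both factors, none of which passed adjustment, were 4q28.1 (36 PGR and 48 FOSL2 regions), 6q24.1 (45 and 66), 8q11.21 (28 and 33), 20p11.23 and 3q25.2 (20 and 20 each) on the PGR side, and 17q25.3 (16 and 99) on the FOSL2 side.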
